A study of Mus musculus with 4 samples.

How the data were processed

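RNA was measured in alveolar epithelial type II cells, the surfactant-producing cells of the lung alveolus, from C57BL/6 mice aged 14 weeks. The labels describe 2 wild-type (WT) samples and 2 samples from mice carrying a conditional active mTOR transgene in the epithelium (mTOR Tg). Per the labels' protocols, total RNA was extracted with an RNeasy Mini kit and libraries followed standard Illumina protocols. The strandedness of the libraries, the sex of the mice, the way the cells were isolated and any batch or date are not given in the sources used here.

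The values used were the deposited whole-number read counts per gene symbol, in a single table covering the 4 libraries. Per the submitters' processing notes, HISAT2 and edgeR were used with the mouse build mm10, with no versions or settings named. The counting program and gene annotation are not given in the sources used here. The columns were tied to samples through the sample names in the labels. The table held 25759 gene symbols, of which 8059 had no count in any library. The library totals were 18146693 and 19018785 counts in WT replicates 1 and 2, and 21972124 and 20273396 counts in mTOR Tg replicates 1 and 2. In libraries of this size 3 counts correspond to 0.137 to 0.165 CPM, the count of a gene scaled to the library total. Exact intervals of count shares and the floors cover counting error only, and reads without molecular identifiers are not independent molecules.

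Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by group (minimum count 10), which left 13306 genes holding 99.9% of all counts. Libraries were scaled with TMM factors, which ranged from 0.928 to 1.04. The quasi-likelihood test (glmQLFit without the legacy option, glmQLFTest) compared mTOR Tg with WT, with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of its F statistic. Normalised CPM are CPM on TMM-scaled library sizes, and log2 CPM used a prior count of 2. The labels do not say whether the samples came from single mice or pools, so p-values measure the spread between these samples. With 2 samples against 2, the smallest two-sided p of an exact permutation test of a single value is 0.333.

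Before the data were examined, 50 gene lists were fixed for metabolism, growth signalling, stress responses, mesenchymal genes and markers of lung cell types, and 45 of them had at least 5 members among the tested genes. Each was tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 45 lists. The same test with an estimated correlation and the self-contained fry test were run beside it. Medians of lists have 95% bootstrap intervals from 1000 resamples of their members. Summed CPM of marker lists are on raw library totals.

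The genes named were chosen by a rule fixed before the data were examined. Those always to be given were Mtor, Sftpc, Angptl4, Cdh1, Cdh2, Vim, Fn1, Snai1, Snai2, Zeb1, Twist1, Acta2 and Tgfb1, along with a gene whose result is not reported here. Genes passing the threshold were to follow by size of change, or, with none passing, the 5 with the smallest p in each direction, as values only. For each list discussed with no passing member, up to 2 members with the smallest p were to be given as values. They are printed below for part of the lists only. Other genes are named as chosen after their values were seen. Gene positions come from GENCODE M21 on GRCm38, the assembly called mm10, and were looked up by symbol.

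The code was tested on simulated counts with the means and library sizes of these libraries and 200 changed genes. With the spread estimated from all 4 libraries, 18% of the genes changed 2-fold and 95% of those changed 4-fold were recovered among 13148 genes, with 17 false calls among 130. With the spread of the WT pair, 99% and 100% were recovered among 13198 genes, with 11 false calls among 234. Each simulation gave both genotypes the same spread, so these shares may be too high where the mTOR Tg libraries vary more than WT. A list shifted 1.5-fold was called by camera at the preset correlation in both simulations. Other lists called were 0 with the spread of all 4 libraries and 1 with that of the WT pair. With an estimated correlation its adjusted p was 0.722 and 0.408, so that setting had little power in this design. The simulated genes were drawn independently, so the simulations cannot show whether the preset correlation of 0.01 holds for these data. Here the estimated correlation ran from -0.15 for B and plasma cell markers to 0.973 for ribosomal proteins.

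The alternatives were other scaling factors (DESeq2's median of ratios, library size only, upper quartile), no filter or a stricter filter on low counts, the robust and legacy options of edgeR, limma-voom, DESeq2 1.42.0, adjusted p thresholds of 0.1 and 0.01, the replicate number as a block, each library left out in turn, and camera on ranks. Added after the data were seen were limma-voom with sample quality weights, DESeq2 on the genes kept by filterByExpr, and a correction of each library for trends on transcript length and GC content. That correction used lowess fits with a span of 0.3 on the longest annotated transcript, which 98.7% of the tested genes had. On simulated counts with an added length trend it took the rank correlation with length from 0.556 to -0.00444 (13186 genes). No GC trend was simulated. In the data the correction took the rank correlation of the deviation of mTOR Tg replicate 1 from -0.585 to 0.115, so a smaller trend of opposite sign was left. The other libraries were left at -0.0589 to -0.0861.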

Results

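Transcript counts were compared between alveolar type II cells of WT mice and of mice with conditionally active mTOR in the epithelium. mTOR is the kinase of the complexes that couple nutrients and growth factors to protein and lipid synthesis. Each genotype had 2 libraries from mice aged 14 weeks, with 18146693 and 19018785 counts for WT and 21972124 and 20273396 counts for mTOR Tg. Between 15985 and 16218 genes had at least 1 count in a library. The comparison asks which transcripts of type II cells differ when mTOR is active, including genes of epithelial to mesenchymal transition, for which the transgenic mouse is known to have been studied.

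Surfactant protein C transcripts (Sftpc, chromosome 14, 70520949 to 70524081), the hallmark of type II cells, made up 7.61% and 6.35% of counts in WT and 6.73% and 7.60% in mTOR Tg. Secretoglobin Scgb1a1, the main secretory product of airway club cells, was also abundant. It took 7.11% (95% exact interval 7.10 to 7.13) and 7.55% (7.54 to 7.56) of counts in WT replicates 1 and 2, 13.9% (13.8 to 13.9) in mTOR Tg replicate 1 and 4.52% (4.51 to 4.53) in replicate 2. The pan-leukocyte gene Ptprc had 0, 3, 0 and 3 counts in WT replicates 1 and 2 and mTOR Tg replicates 1 and 2. No count of the T cell gene Cd3e or the macrophage gene C1qb was found in any library, against a floor of 0.137 to 0.165 CPM. Other genes of leukocyte marker lists were counted, with the B cell gene Cd79b at 194, 177, 255 and 258 counts in the same order and summed alveolar macrophage markers at 78.0 to 102 CPM. The B cell gene Cd79a had 0, 0, 0 and 7 counts and the macrophage gene Marco 0, 0, 0 and 1. Within the alveolar macrophage list Plet1 alone was at 38.8 to 61.1 normalised CPM. Cd79b and the macrophage sum therefore do not by themselves show that such cells were present. Summed club cell markers reached 178280 CPM in mTOR Tg replicate 1, against 94357 and 101510 CPM in WT and 65108 CPM in mTOR Tg replicate 2. Summed ciliated cell markers were 4734 CPM in mTOR Tg replicate 1 and between 2802 and 3440 CPM in the other libraries. Red cell and platelet markers were lowest in mTOR Tg replicate 2, at 1047 CPM against 2555 to 3693 CPM elsewhere. Summed endothelial markers were 292 and 300 CPM in WT and 184 and 234 CPM in mTOR Tg. The summed fibroblast and pericyte markers were 838 and 889 CPM in WT and 1242 and 1181 CPM in mTOR Tg, while the median log2 fold change over the tested members of that list was -0.00 (adjusted p = 0.420).

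**Figure D1:**
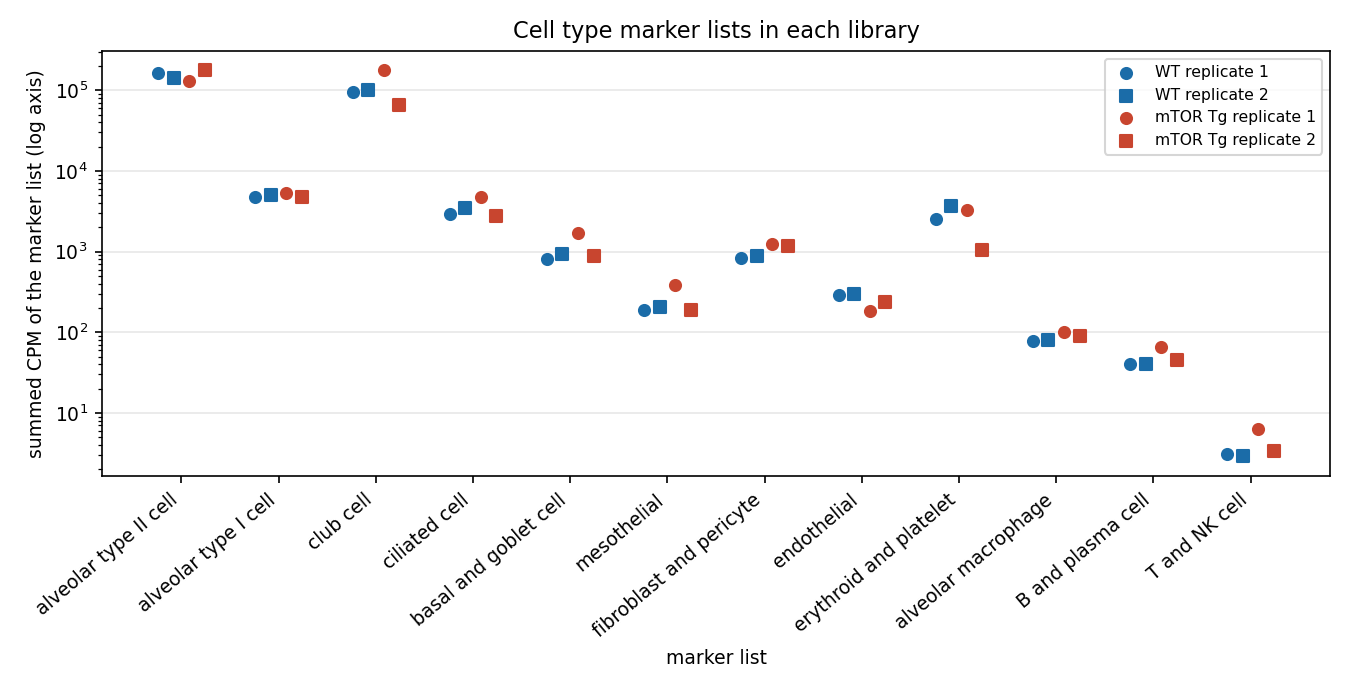
Summed CPM (log axis) of marker lists of 12 cell types, with a point for each of the 4 libraries, blue for WT and red for mTOR Tg, circles for replicate 1 and squares for replicate 2. The club cell sum of mTOR Tg replicate 1 (178280 CPM) lies above the other 3 libraries (65108 to 101510 CPM), and the erythroid and platelet sum of mTOR Tg replicate 2 (1047 CPM) lies below them.

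mTOR Tg replicate 1 stood apart from the other libraries. Its log2 CPM correlated with theirs across genes at Pearson's r of 0.951 to 0.955, where the other 3 libraries correlated with each other at 0.983 to 0.988, and genes are not independent replicates. Between 1807 and 1949 genes lay over 2-fold apart between it and another library, compared with 264 between the WT replicates. Transcript length followed the same split. Genes in the shortest quartile of transcript length had a median log2 deviation of 0.45 from the other 3 libraries in mTOR Tg replicate 1, and genes in the longest quartile a median of -0.56. Mitochondrially encoded transcripts took 3.71% of counts in this library and 4.75% to 4.97% in the others, and as a list they were not called between genotypes (median -0.07, adjusted p = 0.362). The biological coefficient of variation was 0.0891 in the WT pair, 0.325 in the mTOR Tg pair and 0.240 in the fit of all 4 libraries.

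**Figure D2:**
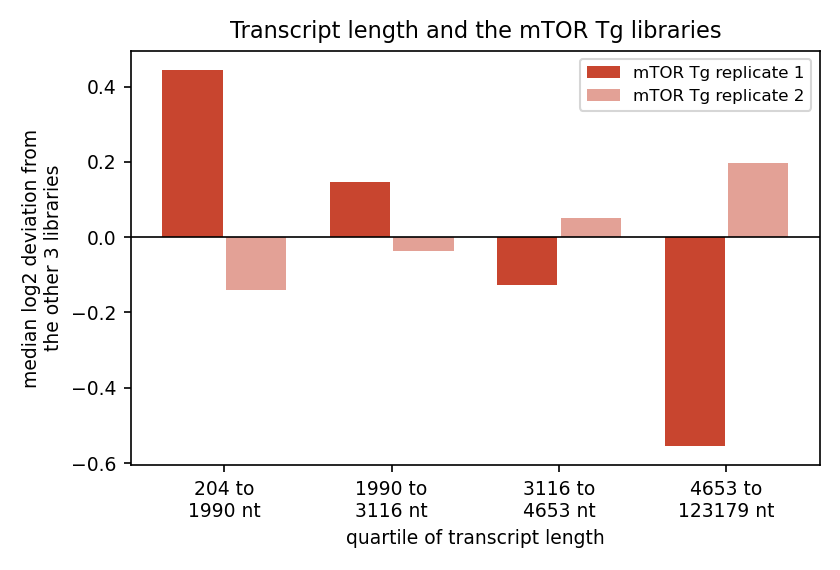
Bars give the median log2 deviation of mTOR Tg replicate 1 (dark) and replicate 2 (pale) from the mean of the other 3 libraries, for the 4 quartiles of transcript length in nucleotides (nt) among tested genes. In replicate 1 the median falls from 0.45 for the shortest transcripts to -0.56 for the longest, and in replicate 2 it goes from -0.14 to 0.20. The mean used for replicate 2 includes replicate 1, so its bars partly mirror the trend of replicate 1 and do not show an opposite trend of their own.

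Angptl4, which encodes a secreted inhibitor of lipoprotein lipase and is a target of PPAR and hypoxia signalling, showed the widest gap among the genes with the smallest p-values that were higher in mTOR Tg and had more than a few WT counts. It was at 1.21 normalised CPM in both WT libraries and at 8.24 and 36.7 CPM in mTOR Tg, from 22, 24, 168 and 767 counts, a log2 fold change of 4.21 (SE 0.78, edgeR adjusted p = 0.860), which was 2.76 without mTOR Tg replicate 2 and 4.92 without mTOR Tg replicate 1. Cxcl5, a neutrophil-attracting chemokine, was at 5.44 and 8.44 CPM in WT and 28.9 and 30.1 CPM in mTOR Tg, a log2 fold change of 2.09 (SE 0.28, edgeR adjusted p = 0.860). The acyl-CoA thioesterase gene Acot1 was at 129 and 141 CPM in WT and 283 and 371 CPM in mTOR Tg. The complement gene C4b was at 7.96 and 8.84 CPM and at 18.3 and 21.1 CPM. Both have near-identical relatives, with which reads can be shared. The lectin gene Clec10a had 1 count in each WT library and 19 and 14 counts in mTOR Tg. Of the genes with the smallest p-values in the other direction, the receptor tyrosine kinase gene Ros1 was at 16.4 and 15.1 CPM in WT and 4.32 and 6.27 CPM in mTOR Tg, a log2 fold change of -1.57 (SE 0.27). The microfibril gene Fbn2 had a log2 fold change of -1.74 (SE 0.31), the transporter gene Slc10a5 of -1.76 (SE 0.33) and the Tudor domain gene Tdrd5 of -1.50 (SE 0.31). Thbs2, which encodes the matricellular protein thrombospondin 2, had 103 and 30 counts in WT and 1 and 2 counts in mTOR Tg. Angptl4 lies on chromosome 17 from 33773750 to 33781830, Cxcl5 on chromosome 5 from 90759360 to 90761624 and Ros1 on chromosome 10 from 52045721 to 52195244.

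None of these genes passed the adjusted threshold. The edgeR quasi-likelihood test called 0 of 13306 genes higher and 0 lower in mTOR Tg, with a smallest adjusted p of 0.860. At an unadjusted p under 0.05 there were 327 genes (205 higher, 122 lower), where chance gives 665. Both mTOR Tg libraries lay above both WT libraries in 2337 genes and below them in 2262, together 34.6% of genes, and chance gives 33.3%. limma-voom also called 0 genes, and DESeq2 called 13 (9 higher, 4 lower), among them Angptl4, Cxcl5, Acot1, Ros1, Slc10a5 and Thbs2. A fit with a library left out has 1 library in a group, whose spread is assumed to equal that of the other group. Calls and p-values from such fits, here and below, therefore hold no replication of that group. Leaving out mTOR Tg replicate 1 gave 299 genes (170 higher, 129 lower), and leaving out mTOR Tg replicate 2 gave 6200 (2976 higher, 3224 lower). Without WT replicate 1 there were 11 genes (10 higher, 1 lower) and without WT replicate 2 there were 15 (11 higher, 4 lower).

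No named gene of epithelial to mesenchymal transition passed the threshold, and the spread within mTOR Tg leaves room for changes larger than the standard errors given. In the simulation with the spread of all 4 libraries, 18% of the genes changed 2-fold were recovered. That simulation gave both genotypes the same spread and drew genes independently, whereas in the data the mTOR Tg pair varied more than the WT pair. Recovery in these data may therefore be lower. E-cadherin (Cdh1) was at 933 ± 1.73 CPM in WT and 877 ± 118 CPM in mTOR Tg (SD, n = 2 each), a log2 fold change of -0.09 (SE 0.22). Vimentin (Vim) had a log2 fold change of -0.14 (SE 0.31), fibronectin (Fn1) of 0.13 (SE 0.26), the repressor of E-cadherin Zeb1 of -0.76 (SE 0.38), smooth muscle actin (Acta2) of -0.68 (SE 0.38) and Tgfb1 of 0.03 (SE 0.24), all with adjusted p of at least 0.860 in edgeR. Cdh2, Snai1, Snai2 and Twist1 had too few counts to be tested. Snai1 had 4 and 6 counts in WT and 7 and 4 in mTOR Tg, Snai2 had 0, 4, 1 and 2, Twist1 had 0, 1, 0 and 0, and Cdh2 had 4, 9, 4 and 10 in the same order. The kinase gene Mtor itself (chromosome 4, 148448611 to 148557683) was at 56.8 and 56.7 CPM in WT and 38.9 and 61.8 CPM in mTOR Tg. Whether transcripts of the transgene are counted under this symbol is not given in the sources used here, so this count does not check the labels. The log2 fold change of Mtor was -0.55 without mTOR Tg replicate 2 and 0.12 without mTOR Tg replicate 1. That of Zeb1 was -1.17 and -0.45 in the same order, and that of Acta2 was -0.32 and -1.15. With 1 library left out, the log2 fold change ranged from -0.23 to 0.04 for Cdh1, from -0.45 to 0.25 for Vim, from -0.04 to 0.29 for Fn1 and from -0.14 to 0.22 for Tgfb1, with no call.

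**Figure D3:**
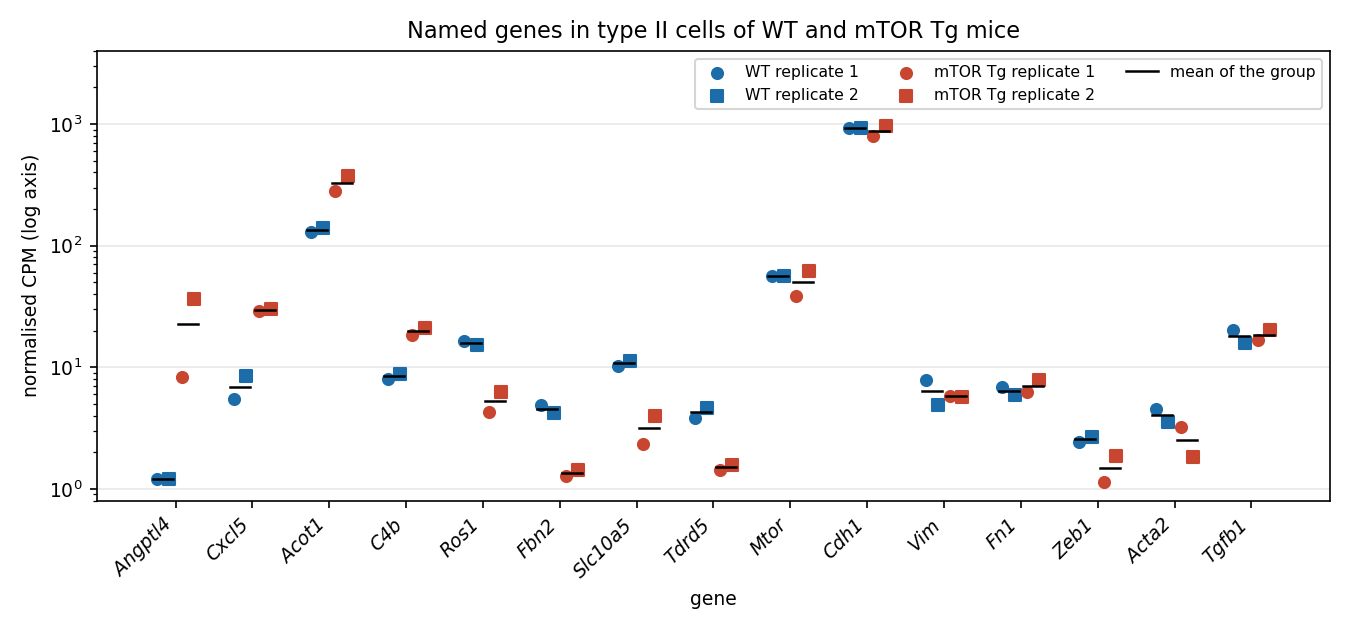
Normalised CPM (log axis) of 15 named genes in the 4 libraries, blue for WT and red for mTOR Tg, circles for replicate 1 and squares for replicate 2, with a bar at the mean of each group. Angptl4 lies at 1.21 CPM in both WT libraries and at 8.24 and 36.7 CPM in mTOR Tg, while Cdh1, Vim, Fn1 and Tgfb1 overlap between the genotypes.

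Of the 45 gene lists tested, camera called 16 at the preset correlation, 13 higher and 3 lower in mTOR Tg. None of the 16 was called with an estimated correlation, and fry called 2. Targets of NRF2, the transcription factor of antioxidant defence, were higher as a group in mTOR Tg, with positive log2 fold changes in 28 of 30 members and a median of 0.47 (95% interval 0.39 to 0.57). The list median lay above WT in both mTOR Tg libraries, by 0.45 in replicate 1 and 0.36 in replicate 2, where the WT replicates differed by 0.02. The camera adjusted p was 1.44e-09, against an adjusted p = 0.694 with an estimated correlation and 0.0119 in fry. The carbonyl reductase gene Cbr3 was at 26.0 and 26.3 CPM in WT and 52.0 and 80.4 CPM in mTOR Tg, and the glutathione peroxidase gene Gpx2 at 66.4 and 74.4 CPM and at 148 and 97.3 CPM. Genes of the ATF4 amino acid response, of which 8 of 31 stand in another list too, were higher as a group, with a median log2 fold change of 0.33 and 23 positive members. Its median lay 0.50 and 0.36 above WT in mTOR Tg replicates 1 and 2, with an adjusted p of 8.05e-06 by camera, an adjusted p = 0.694 with an estimated correlation and 0.0261 by fry. The mitochondrial folate enzyme gene Mthfd2 was at 1.48 and 1.57 CPM in WT and 4.07 and 5.70 CPM in mTOR Tg, and the transcription factor gene Atf5 at 35.4 and 34.9 CPM and at 69.0 and 58.8 CPM. The ATF4 list had a median of 0.50 (adjusted p = 0.0398) without mTOR Tg replicate 2.

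PPAR target genes, which serve fatty acid handling, were also higher as a group, with a median log2 fold change of 0.38 and 18 of 25 members positive. The list median was 0.23 above WT in mTOR Tg replicate 1 and 0.34 in replicate 2, with a camera adjusted p of 3.98e-08 and an adjusted p = 0.805 with an estimated correlation. Acot1 and Angptl4 passed when adjusted over the list alone (2 of 25), and 0 members passed over all genes. Without mTOR Tg replicate 2 the list was no longer called (median 0.23, adjusted p = 0.0873). Angptl4 and the lipid droplet gene Plin2, at 105 and 98.9 CPM in WT and 171 and 290 CPM in mTOR Tg, also belong to the hypoxia list. That list was not called (median 0.09, adjusted p = 0.139), and Angptl4 was its 1 member that passed when adjusted over the list alone. The hypoxia median was 0.15 without mTOR Tg replicate 1 and 0.20 without WT replicate 1. Fatty acid synthesis genes were lower as a group, with 16 of 17 members negative and a median of -0.34. That median was -0.58 in mTOR Tg replicate 1 and -0.12 in replicate 2 (camera adjusted p = 3.30e-05, and adjusted p = 0.805 with an estimated correlation). The desaturase gene Fads2 was at 62.3 and 57.6 CPM in WT and 32.9 and 43.5 CPM in mTOR Tg, and Scd2 at 1520 and 1297 CPM and at 553 and 1039 CPM. Without mTOR Tg replicate 1 the median of the fatty acid synthesis list was -0.13, against -0.34 with all libraries, and the list was no longer called. After the length and GC correction this list lay at -0.578 and -0.132 against WT in mTOR Tg replicates 1 and 2, and type II cell markers at -0.529 and 0.2. Whether a lower share of type II cells contributes in replicate 1 was not tested.

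Markers of other lung cells moved in both directions. Endothelial markers were lower as a group, with 23 of 26 members negative and a median log2 fold change of -0.44, at -0.70 in mTOR Tg replicate 1 and -0.26 in replicate 2. The camera adjusted p was 2.04e-07 and the adjusted p = 0.805 with an estimated correlation. The VEGF receptor gene Kdr was at 79.3 and 84.4 CPM in WT and 51.9 and 35.0 CPM in mTOR Tg, and the carbonic anhydrase gene Car4 at 1.37 and 1.36 CPM and at 0.343 and 0.335 CPM. Without mTOR Tg replicate 1 the median was -0.27 (adjusted p = 0.000945) and without mTOR Tg replicate 2 it was -0.78 (adjusted p = 0.0133). Mesothelial markers were higher as a group (median 0.68 over 9 members, camera adjusted p = 8.05e-06, and adjusted p = 0.805 with an estimated correlation), with Upk3b at 2.47 and 3.49 CPM in WT and 7.65 and 7.61 CPM in mTOR Tg. Their median lay 1.10 and 0.49 above WT in mTOR Tg replicates 1 and 2, but their summed CPM was 191 and 208 in WT, 385 in mTOR Tg replicate 1 and 188 in replicate 2. The median also differed by 0.66 between the WT replicates, and it was 0.40 without WT replicate 1, 1.45 without WT replicate 2, 0.21 without mTOR Tg replicate 1 and 1.08 without mTOR Tg replicate 2, and 0.41 after the length and GC correction. Upk3b and Nkain4 passed when adjusted over this list alone. Alveolar type I markers, of which 8 of 23 stand in another list, were higher as a group (median 0.25, adjusted p = 0.000663, and adjusted p = 0.805 with an estimated correlation), by 0.44 in mTOR Tg replicate 1 and 0.10 in replicate 2. Of these, Igfbp2 had a log2 fold change of 1.62 (SE 0.51), which was 0.70 without mTOR Tg replicate 1 and 2.17 without mTOR Tg replicate 2, and Cyp2b10 was at 118 and 116 CPM in WT and 250 and 171 CPM in mTOR Tg. The median was 0.10 without mTOR Tg replicate 1 and 0.44 without mTOR Tg replicate 2, and 0.17 without WT replicate 1. Antigen presentation genes were higher as a group (median 0.27, adjusted p = 0.00117, and adjusted p = 0.805 with an estimated correlation), by 0.21 and 0.34 in the mTOR Tg libraries, while the WT replicates differed by -0.28. After the length and GC correction the median was 0.07 (adjusted p = 0.472). The median was 0.16 (adjusted p = 0.209) without WT replicate 2, 0.21 (0.452) without mTOR Tg replicate 2 and 0.45 (0.000141) without WT replicate 1. H2-Q7, a class I gene of a family with near-identical copies, was at 6.75 and 4.65 CPM in WT and 9.03 and 19.5 CPM in mTOR Tg.

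The other called lists followed mTOR Tg replicate 1, the library with more short transcripts and more club cell transcripts. The transitional alveolar state, an intermediate between type II and type I cells, had a median of 0.87 above WT in this library and 0.09 in replicate 2 (adjusted p = 5.09e-06, and adjusted p = 0.805 with an estimated correlation). In this list 14 of 25 members stand in another list too. Of its members, Gdf15 was at 13.1 and 19.7 CPM in WT and 31.5 and 31.4 CPM in mTOR Tg, and Clu at 199 and 183 CPM and at 359 and 287 CPM. Its median was 0.09 (adjusted p = 0.0767) without mTOR Tg replicate 1. Ciliated cell markers lay 1.08 above WT in replicate 1 and -0.04 in replicate 2, nuclear genes of oxidative phosphorylation 0.51 and -0.03, proteasome genes 0.52 and 0.02, ribosomal protein genes 0.47 and -0.14, aminoacyl-tRNA synthetase genes 0.33 and 0.05, and glycolysis genes 0.43 and -0.01. Sterol biosynthesis genes lay at -0.64 and -0.01. Adjusted p-values by camera were 0.000661, 0.000136, 0.000184, 0.000663, 0.0227, 0.0332 and 0.0312 in the same order. With an estimated correlation the adjusted p was 0.805 for 5 of these 7 lists, 0.816 for oxidative phosphorylation and 0.871 for ribosomal proteins. Without mTOR Tg replicate 1 the ribosomal protein list was lower in mTOR Tg (median -0.14, adjusted p = 0.000126). The others were not called without that library, with medians of -0.04 for ciliated markers, -0.04 for oxidative phosphorylation, 0.02 for the proteasome, 0.05 for the synthetases, -0.02 for glycolysis and -0.02 for sterol synthesis. Calls were also lost without WT replicate 2 for ribosomal proteins (median 0.11 against 0.20 with all libraries, adjusted p = 0.181), glycolysis (0.18 against 0.22, 0.149) and the synthetases (0.17 against 0.20, 0.0947). Without WT replicate 1 this held for the synthetases (0.21, 0.118) and sterol synthesis (-0.15 against -0.21, 0.428). The length and GC correction ended the call of glycolysis (median 0.06, adjusted p = 0.284) and of oxidative phosphorylation (-0.03, 0.700), and turned that of ribosomal proteins to lower in mTOR Tg (-0.12, 0.00100). Lists that stayed called had smaller medians, from 0.48 to 0.19 for the transitional state, from 0.28 to 0.13 for the proteasome, from 0.65 to 0.39 for ciliated markers and from 0.20 to 0.12 for the synthetases, while sterol synthesis went from -0.21 to -0.23 (adjusted p = 0.000926). Among members, the synthetase gene Cars had a log2 fold change of 0.56 (SE 0.19), and the sterol gene Pmvk was at 78.1 and 70.1 CPM in WT and 187 and 86.3 CPM in mTOR Tg. Pmvk goes against its list, in which 20 of 23 members had negative log2 fold changes and 3 positive.

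**Figure D4:**
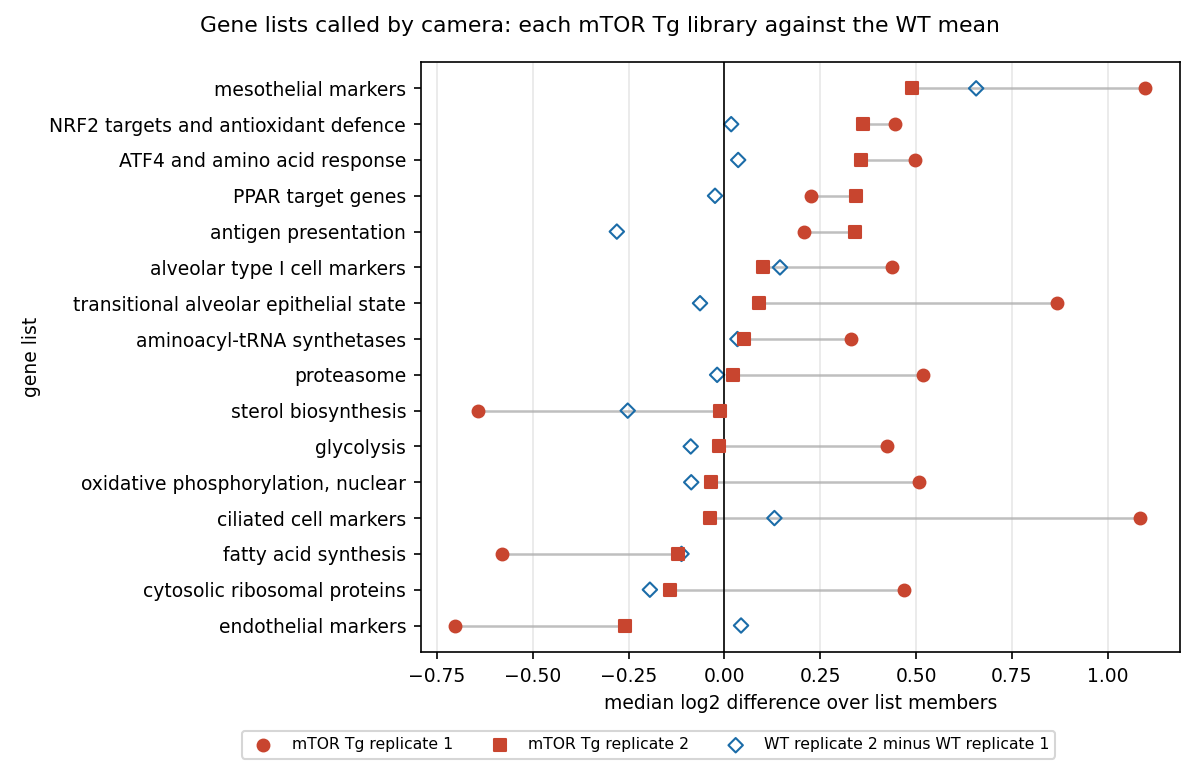
Median log2 difference over the members of each of the 16 called lists, for mTOR Tg replicate 1 (red circles) and replicate 2 (red squares) against the mean of the WT libraries, and for WT replicate 2 against WT replicate 1 (open diamonds). The NRF2, ATF4, PPAR and antigen presentation lists have both red points on the same side at 0.21 to 0.50, while the ciliated and transitional lists lie at 1.08 and 0.87 in replicate 1 and near 0 in replicate 2.

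Components of the mTOR pathway were not called as a group, with 17 of 34 members positive and a median log2 fold change of 0.02 (adjusted p = 0.816). Eif4ebp1, the translation repressor that mTOR phosphorylates, had a log2 fold change of 0.65 (SE 0.22), and the stress-induced inhibitor gene Sesn3 was at 78.7 and 79.5 CPM in WT and 29.1 and 71.8 CPM in mTOR Tg. Ribosome biogenesis genes (median 0.12, adjusted p = 0.417), lysosome and TFEB targets (0.13, 0.210), autophagy genes (0.08, 0.369), unfolded protein response genes (0.15, 0.139) and nucleotide synthesis genes (0.07, 0.311) were not called. Mesenchymal genes of epithelial to mesenchymal transition (median 0.11, adjusted p = 0.826), TGF-beta response genes (-0.06, 0.698), extracellular matrix genes (0.05, 0.427) and epithelial junction and keratin genes (-0.08, 0.947) were not called either. Without mTOR Tg replicate 1 the mesenchymal median was 0.32 and the matrix median 0.35, and without mTOR Tg replicate 2 they were -0.26 and -0.18. Each of these fits rests on 1 mTOR Tg library. In the mesenchymal list Tagln had a log2 fold change of -0.88 (SE 0.37) and Lox of 1.06 (SE 0.46) with all libraries. Type II cell markers had a median of -0.05 (adjusted p = 0.826) with all libraries. Against WT their median lay at -0.16 in mTOR Tg replicate 1 and at 0.19 in replicate 2. Club cell markers had a median of 0.25 (adjusted p = 0.208). That median was -0.43 without mTOR Tg replicate 1, 0.67 without mTOR Tg replicate 2 and 0.34 without WT replicate 2. Surfactant lipid genes (-0.03, 0.826), cell cycle genes (0.03, 0.311), interferon-stimulated genes (0.16, 0.698) and inflammatory cytokines (0.21, 0.141) were not called, although Cxcl5 passed when adjusted over the cytokine list alone. Without mTOR Tg replicate 1 the medians were 0.25 for the cytokines, 0.09 for the lysosome list and 0.15 for the unfolded protein response. That of cell cycle genes was 0.14 without WT replicate 1. Erythroid and platelet markers (-0.42, 0.126) were not called, and their median was -1.33 without mTOR Tg replicate 1 and -0.68 without WT replicate 1. Basal and goblet cell markers (0.30, 0.204) were not called, and their median was 0.45 without mTOR Tg replicate 2 and 0.54 without WT replicate 2. The length and GC correction brought a call of the matrix list (0.22, 0.000940). The median, mean and test differed in sign in 6 lists, namely the mTOR components, the mesenchymal genes, the junction genes, alveolar macrophage markers, immediate early genes and growth factors.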

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

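Sample quality weights, DESeq2 after the edgeR filter and the length and GC correction were chosen after the data were seen. Against 0 genes differing, DESeq2 gave 13 (9 higher, 4 lower), DESeq2 after the filter 12 (9 and 3) and leaving out a library 11 to 6200 (10 to 2976 higher, 1 to 3224 lower). Every other setting gave 0 except the replicate number as a block. That block gave 37 (22 and 15), and the labels do not say whether replicate numbers pair samples. The WT and mTOR Tg replicate differences correlated at 0.0708 across genes. This cannot exclude a pairing, since 1949 genes lay over 2-fold apart in the mTOR Tg pair against 264 in the WT pair, which could hide a shared difference. The 16 lists called became 0 with an estimated correlation and 2 with fry, and 13 to 18 under the other settings. Leaving out 1 library turned the direction of 8 lists that were called either with all libraries or in that same fit, with medians of -0.14 to 0.46 for ribosomal proteins, -0.0207 to 0.42 for glycolysis, -0.0361 to 0.50 for oxidative phosphorylation, -0.26 to 0.32 for mesenchymal genes, -0.17 to 0.19 for type II markers, -0.43 to 0.67 for club markers, -0.0429 to 1.09 for ciliated markers and -0.41 to 0.30 for immediate early genes. In each the direction of the test turned without mTOR Tg replicate 1, and a library left alone in its group is assumed to vary like the other group. The correction ended the calls of antigen presentation (0.07, adjusted p = 0.472) and glycolysis (0.06, 0.284) and added those of the matrix list (0.22, 0.000940) and the erythroid and platelet list (-0.88, 2.92e-05). It also ended the call of oxidative phosphorylation (-0.0331, 0.700) and turned that of ribosomal proteins (-0.12, 0.00100), and length was not separated from GC. The cause of these changes was not tested. Of 899 recomputed list values 820 kept their call or absence of a call, 48 calls were lost, 21 gained and 10 values turned as above, and 37 of the 820 were sign changes of lists not called either way. Of 1896 values of named genes 1755 stayed without a call, 16 of them with a changed sign, and 141 calls were gained. Scaling moved the median of all genes by under 0.1 in log2. Depth limits genes below about 0.165 CPM, where 3 counts are the floor.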

Other observations

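The genes in this paragraph and the next were chosen after their values were seen. None passed the adjusted threshold in the main edgeR fit, while DESeq2 called Hspb1, Mt2, Cyp2a5 and Adamts1. With the replicate number as a block, edgeR called these and Pdk4, Slc7a11, Hspa1a and Hspa1b. The fixed list of immediate early and dissociation stress genes, which includes heat-shock genes, was not called, with 15 members positive and 15 negative and medians of 0.41 and -0.41 in mTOR Tg replicates 1 and 2. The genes picked from it and beside it were therefore not a tested group. The small heat-shock protein gene Hspb1 was at 161 and 135 CPM in WT and 495 and 297 CPM in mTOR Tg (log2 fold change 1.42, SE 0.30). The mitochondrial chaperonin genes Hspe1 and Hspd1, which share a promoter region, had log2 fold changes of 1.16 (SE 0.28) and 0.74 (SE 0.20). Hsp90aa1 was at 654 and 828 CPM in WT and 1372 and 1337 CPM in mTOR Tg, and its co-chaperone gene Stip1 at 131 and 159 CPM and at 356 and 219 CPM. The inducible Hsp70 genes differed within each genotype, with Hspa1a at 1170 and 149 CPM in WT and 193 and 26.6 CPM in mTOR Tg, so that WT replicate 1 lay above the rest. Hspa1b, its near-identical neighbour, was at 1385, 237, 431 and 38.5 CPM in the same order.

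The metallothionein genes Mt1 and Mt2 were at 71.0 and 55.0 CPM and at 11.8 and 7.23 CPM in WT, and at 129 and 119 CPM and at 24.8 and 33.7 CPM in mTOR Tg. The cytochrome P450 gene Cyp2a5, one of a family with close copies, was at 26.2 and 42.6 CPM in WT and 93.6 and 132 CPM in mTOR Tg. Pdk4, which restrains pyruvate oxidation, was at 6.09 and 7.23 CPM in WT and 11.9 and 26.1 CPM in mTOR Tg. Adamts1, a secreted protease gene, was at 112 and 70.7 CPM in WT and 20.9 and 41.6 CPM in mTOR Tg. The cystine transporter gene Slc7a11 differed within the mTOR Tg group, at 2.42 and 2.63 CPM in WT, 2.65 CPM in mTOR Tg replicate 1 and 55.2 CPM in replicate 2.

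Of the tests that follow, those on markers of all other cell types, on airway cells as a source of the NRF2, PPAR and ATF4 differences, on length for these lists and on neighbouring genes were chosen after the result was seen. mTOR Tg replicate 1 stands apart from the other 3 libraries. Its type II marker median lay at -0.225 against the other 3 (member interval -0.671 to -0.133), and at -0.604 after the length and GC correction. A drop in the share of type II cells alone would raise the markers of every other cell type. The endothelial median of this library lay at -0.653 against the other 3 while its club, ciliated and mesothelial medians lay above 0, so such a drop cannot be the only change. Endothelial markers were also lower in mTOR Tg replicate 2, at -0.26 against WT. A lower type II share beside other changes was not tested. The rank correlation of the deviation of mTOR Tg replicate 1 with transcript length across genes was -0.585, larger in size than in the other libraries (0.297, 0.556 and 0.389). Those values are not independent of it, since the mean that each is set against includes mTOR Tg replicate 1. A trend with length in this library, as RNA quality or library preparation could give, may contribute. A larger share of airway cells may contribute too, since after the length and GC correction the club and ciliated medians both stayed at or above 0.501. Whether length and GC make up the rest cannot be told apart from other sources, as the corrected deviation was still 1.75 times the largest of the other libraries, between the values set beforehand, and an effect of genotype in this library alone was not testable.

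The NRF2, PPAR and ATF4 lists lay above WT in both mTOR Tg libraries, although those libraries differ so much. A larger share of airway cells does not account for replicate 2, where the club median was -0.38 and the lowest of the 3 list medians 0.344, but cannot be told apart in replicate 1, where the club median of 0.67 and the lowest list median of 0.227 were both above WT. In mTOR Tg replicate 2 the length and GC correction left the NRF2 median at 0.35 and the PPAR median at 0.341. The length and GC trend therefore does not account for these differences in that library. In replicate 1 the correction lowered NRF2 from 0.446 to 0.204. It lowered PPAR there from 0.227, with an interval of -0.14 to 0.546, to 0.111, the lowest corrected median. The corrected member intervals lay above 0, the closest bound being 0.00996, but they cover the spread over list members and not between samples. The correction also left a length trend of opposite sign in replicate 1. How far the length and GC trend explains the NRF2 and PPAR differences in replicate 1 therefore cannot be told. For the ATF4 list the lowest corrected median was 0.208 with an interval from -0.0184 to 0.442, so that trend cannot be told apart from a difference by genotype in replicate 1, although replicate 2 stayed at 0.346 and the list was still called (median 0.30, adjusted p = 0.000130). A response to the transgene is a possible explanation that stays untested against mouse-to-mouse variation, sex, handling or litter. A fixed list of sex-linked transcripts summed to 103 and 110 CPM in WT and to 57.1 and 90.2 CPM in mTOR Tg. That list was drawn up with both Xist and genes of the Y chromosome, so its sum does not tell the sex of the mice.

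Among the 3 splits of the 4 libraries into 2 and 2, the real split called 16 lists and the highest other split 22, and 2 splits called at least as many as the real one. So few splits cannot give a share under 0.05. In the split with 22 lists, which sets WT replicate 2 and mTOR Tg replicate 1 against the other pair, the camera adjusted p was 0.856 for NRF2, 0.829 for ATF4 and 0.00779 for PPAR. In the split of replicates 2 against replicates 1, which called 9 lists, these were 0.979, 0.979 and 0.0919. The NRF2, ATF4 and PPAR lists had been picked because their medians lay above WT in both mTOR Tg libraries. Each of the other splits puts the mTOR Tg libraries on opposite sides, so a shift shared by both cancels. High values in those splits were therefore largely fixed by that choice and are no evidence for an effect of genotype.

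The 100 genes with the smallest p held 21 pairs within 1 Mb of each other, and only 0.2% of 1000 random sets of similar expression held as many. The pairs lay on 11 chromosomes and included Angptl4 with C4b on chromosome 17, Mt1 with Mt2 and Hspe1 with Hspd1. Strain DNA linked to an inserted transgene would give such pairs, but so would neighbours that vary together in any comparison. The split of replicates 2 against replicates 1, unrelated to genotype, gave 20 pairs and the remaining split 9. DNA linked to an insertion would lie near it, so the spread over 11 chromosomes argues against it as the source of all the pairs. For pairs in a single region, such as those of Angptl4, C4b, Gm20547 and Nrm on chromosome 17, linked DNA cannot be told apart from that tendency. Variants in the reads were not analysed here.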
